A study of Mus musculus with 16 samples.

How the data were processed

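RNA-seq and ATAC-seq were measured in monocytes sorted from the spleens of 7-day-old C57BL/6 mice into a fraction with high and a fraction with low surface Nrp1 (neuropilin-1, a co-receptor for semaphorins and VEGF). ATAC-seq cuts open chromatin with a transposase, so that read density marks accessible DNA. The 16 libraries were 6 for RNA (3 Nrp1 high, 3 Nrp1 low, 80000 cells each) and 10 for ATAC (5 and 5, 50000 cells each). The cell type label of every sample is myeloid-derived suppressor cell, and the protocol calls the sorted cells monocytes. Groups and replicate numbers were taken from the sample titles. The descriptions of the RNA samples name them Nrp1_neg_M_MDSC where the title says Nrp1 low, and Nrp1_pos_M_MDSC where it says Nrp1 high. The markers of the sorting gate other than Nrp1 are not given in the sources used here.

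Per the labels' protocols, RNA libraries were made with a template-switching kit for low input and read in pairs of 150 bases. The authors aligned to GRCm38, and HISAT2 and StringTie are among the tools, given without versions, in the submitters' processing notes. The deposited values are estimated counts per gene. They are whole numbers, so rounding changed nothing, and the layout of gene identifier and symbol is that of the count script distributed with StringTie, which derives counts from coverage. In every library the value 4 was more frequent than the mean of its neighbours 3 and 5, by 1.22 to 1.53 times, so the scale of a count is uncertain, and counting error may be larger than the counts state. The table held 25562 genes, each with at least 1 count in total. Strand was not stated, so overlapping and antisense genes, and near-identical families such as the stefins, are uncertain.

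For ATAC-seq, the authors deposited the result of their own comparison, with a log2 fold, a p-value and an FDR for each of 40796 regions. No value per library was used here, so the depth of these libraries is unknown and no replicate could be left out. Trimmomatic, BWA, Picard, MACS2, DiffBind, edgeR, DESeq2 and ChIPseeker are among the tools in the submitters' processing notes. Whether reads were shifted for the transposase, and which of the 10 libraries entered, is not given in the sources used here. The library names in the labels have 2 styles, 1 for replicates 1 and 2 and another for replicates 3, 4 and 5 of both groups, and no check of this split was possible. The direction of the fold, high against low, rests on the name the labels give the comparison, and no column of the deposited table states it. The labels of these samples name a table made with DESeq2, while the deposited table used here is named for edgeR, so the labels may describe another table. The deposited FDR differed from a Benjamini-Hochberg adjustment of the deposited p-values over the listed regions by at most 0.00027. Regions were 400 bases wide in 99.2% of cases, and coordinates are on GRCm38 as deposited. Gene coordinates come from RefSeq on GRCm38.p6.

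Genes were kept with edgeR's filterByExpr (15541 genes), scaled by TMM and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, robust, group as the term). Adjusted p-values are Benjamini-Hochberg values, and a gene was called under 0.05. Log2 fold changes are Nrp1 high minus Nrp1 low, with their standard errors (SE). Levels are CPM at TMM-scaled library sizes, as mean ± SD over 3 libraries. Single genes fixed beforehand were also compared by a two-sided exact permutation test on log2(CPM + 1), whose smallest p with 3 against 3 libraries is 0.1. The labels do not say whether libraries came from separate animals and speak of pooled RNA, so p-values measure the spread between these libraries, which may be technical.

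The 44 gene lists were fixed before the data were examined, as were the tests, the groups and the rule for named genes. Of 1132 list entries, 1107 matched the table and 1030 were tested. Lists were tested with camera (limma 3.58.1, two-sided, preset correlation 0.01), again with an estimated correlation, and with fry. The genes named are Nrp1, Sema4a, Klf4, Nos2, Mapk14 and Mtor. To these were added up to 12 called genes per direction with the largest change, a mean of at least 10 CPM, groups that did not overlap and a symbol that is not a predicted model, and up to 4 members of each list with the lowest p. For ATAC the rule takes the region of lowest FDR for the first 2 sets and the 5 regions of largest positive and of largest negative fold. Other genes are named as chosen after their values were seen.

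Promoter regions lay within 3000 bases of a transcript start. Genes past both thresholds were compared by Fisher's exact test, two-sided, and all genes tested in RNA with a promoter region by Spearman's rho and Pearson's r with 100000 permutations (scipy, Python 3). Alternatives were RLE and upper-quartile factors, library totals, DESeq2 1.42.0, limma-voom, other filters and thresholds, the replicate number as a block, leaving out each RNA library, other promoter distances and other ATAC thresholds. On simulated counts of 14937 genes for this comparison, edgeR recovered 82% of 4-fold and 7% of 2-fold changes, with 8 false calls. On simulated counts of 15541 genes, DESeq2 recovered 95% of 4-fold and 31% of 2-fold changes, with 58 false calls. The promoter comparison was tested on simulated data with a correlation of 0.3 over 5000 genes and returned 0.312.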

Results

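Transcripts and open chromatin were compared between Nrp1 high and Nrp1 low monocytes of the neonatal mouse spleen. Total counts of the 3 Nrp1 low RNA libraries were 35127433, 23395363 and 26962442, and those of the 3 Nrp1 high libraries 28866801, 31428419 and 28440098. Correlations between libraries of log2 CPM lay between 0.859 and 0.954. The first principal component held 49% of the variance, and on it Nrp1 low replicate 1 lay farthest from the others (-133.3, against -22.84 to 71.07). Mitochondrially encoded genes took 0.784, 1.57 and 1.11% of the counts in the low libraries and 3.01, 1.29 and 2.38% in the high libraries. The transcript CT010467.1 took 0.127, 0.905 and 0.556% in the low libraries against 1.60, 0.834 and 1.63% in the high libraries.

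The RNA comparison asks which transcripts differ between the fractions sorted by Nrp1. Nrp1 (ENSMUSG00000025810, chromosome 8, 128358591 to 128505476) stood at 99.5 ± 10.98 CPM (SD, n = 3) in Nrp1 high and 39.8 ± 18.9 CPM in Nrp1 low monocytes, 2.50-fold. The 3 high libraries held 97.3, 89.8 and 111.4 CPM, all above the low libraries at 20.1, 57.8 and 41.5 CPM. The log2 difference was 1.32 ± 0.36 (SE). It did not pass edgeR's quasi-likelihood test over all genes (adjusted p = 0.259), passed with DESeq2 (adjusted p = 0.0187), and ranged from an adjusted p of 0.0187 to 0.785 over the alternatives run. The exact permutation p for Nrp1 was 0.1, the smallest this design allows.

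The other genes fixed as subjects did not pass the test. Klf4 (ENSMUSG00000003032), a zinc finger transcription factor of monocytes, stood at 190.5 ± 66.6 CPM in Nrp1 high and 74.9 ± 53.6 CPM in Nrp1 low (n = 3 each; log2 difference 1.35 ± 0.62 SE, adjusted p = 0.445). Nrp1 low replicate 1 held 17.1 CPM of Klf4 and the other low libraries 122.9 and 84.8. Sema4a, which encodes a transmembrane semaphorin, stood at 251.2 ± 45.7 against 307.2 ± 46.2 CPM (adjusted p = 0.533). Mapk14, the gene of p38 alpha, stood at 222.0 ± 25.9 against 203.6 ± 16.7 CPM (adjusted p = 0.743). Mtor, the kinase of the mTOR complexes, stood at 34.2 ± 8.22 against 23.2 ± 7.70 CPM (adjusted p = 0.475). Nos2, inducible nitric oxide synthase, has no row in the count table and was not analysed here in RNA. Every gene in that table has a count in some library, so a gene with none would be missing. Whether this is why Nos2 is missing was not tested.

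Genes of granulocyte granules were lower in Nrp1 high monocytes. Camp, which encodes the cathelicidin of secondary granules, fell from 8417 ± 2238 CPM in Nrp1 low to 643.2 ± 62.5 CPM in Nrp1 high (n = 3 each), 13.1-fold. Ngp, the neutrophilic granule protein, fell from 12327 ± 2955 to 1065 ± 305.6 CPM, 11.6-fold. Chil3, a chitinase-like protein of myeloid cells, fell from 2309 ± 527.8 to 212.0 ± 22.9 CPM, 10.9-fold. S100a9, a subunit of the calcium-binding protein calprotectin, fell from 9244 ± 3176 to 1164 ± 275.4 CPM, 7.94-fold.

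Of 15541 genes tested, 106 were called by edgeR's quasi-likelihood test at adjusted p under 0.05. Of these 105 were lower and 1 higher in Nrp1 high. The median log2 fold change of the 105 lower genes was -2.26, or 4.78-fold, also with Chit1 at a floor of 3 counts per library. In all 106 genes the 3 libraries of each group did not overlap. The call itself selects such genes, so this adds no support. Among all tested genes 20.3% did not overlap, against the 10% that chance gives. At an unadjusted p under 0.05, 699 genes were higher and 1045 lower. Chil1, another chitinase-like protein, was 9.33-fold lower, Tuba8, an alpha tubulin, 8.81-fold, Itgb2l, an integrin beta subunit, 8.50-fold, and Mogat2, an enzyme of triacylglycerol synthesis, 8.02-fold. Cstdc4, Cstdc5 and Cstdc6, of the stefin family of protease inhibitors, had log2 fold changes of -3.04, -3.31 and -3.34. Mrgpra2a, a G protein-coupled receptor, had -2.99. These last 4 have near-identical copies that share reads, so their single values are uncertain. Chit1, the chitotriosidase gene, was at 4.60 ± 1.21 CPM in Nrp1 low and at 0 in all 3 high libraries, and no fold is given, since the scale of a count is uncertain. The only gene called higher was Ugt1a6a, a glucuronosyltransferase, at 27.0 ± 7.04 against 6.50 ± 1.28 CPM (log2 2.06 ± 0.31 SE, adjusted p = 0.0289). It shares exons with the other genes of its cluster, and it was no longer called in 5 of the 6 fits that leave out a library, with adjusted p between 0.0796 and 0.193, the exception being the fit without Nrp1 low replicate 1.

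The number of genes called by edgeR was 0 without Nrp1 high replicate 3 (909 at unadjusted p under 0.05), 28 without high replicate 1, 29 without low replicate 3 and 50 without high replicate 2, while all 106 genes kept their sign in each of these fits. With the replicate number as a block edgeR also called 0 genes (943 at unadjusted p under 0.05), and all 106 kept their sign. The groups did not overlap in any of the 106 genes, so these fits could hardly turn a sign. The kept signs therefore add no support. DESeq2 called 393 genes, 81 higher and 312 lower, so its share of higher calls was 20.6%. On simulated counts for this comparison DESeq2 made 58 false calls and edgeR 8.

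**Figure D1:**
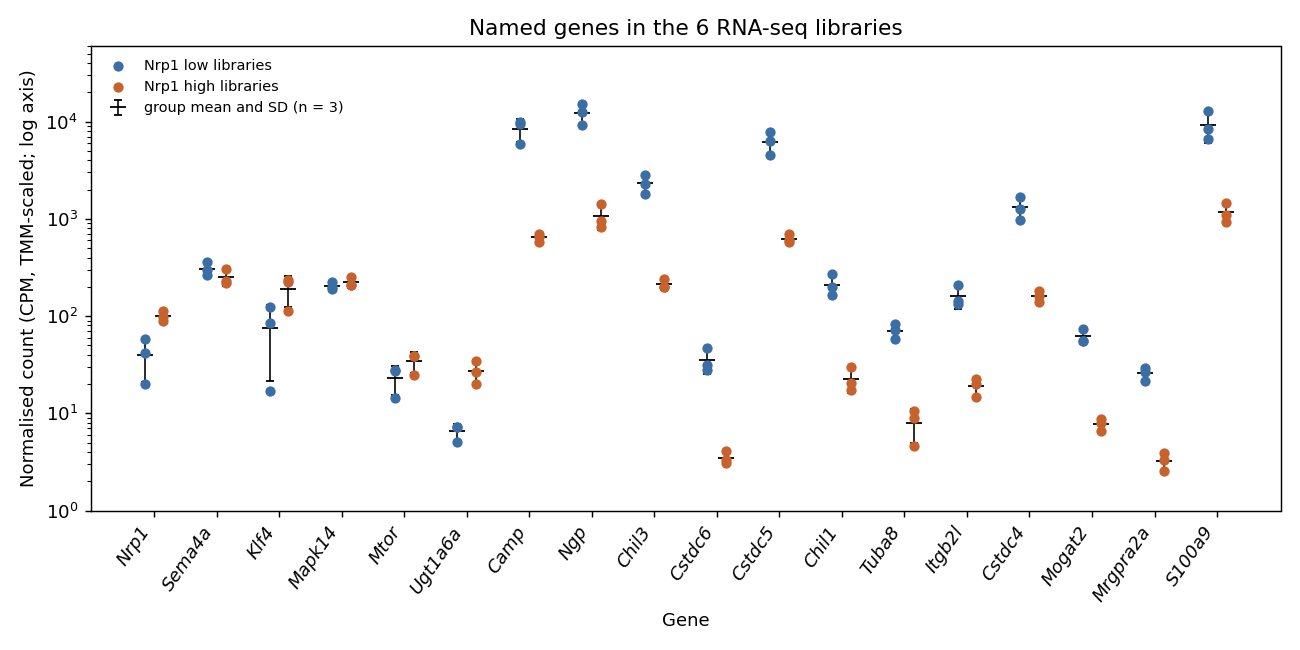
Normalised counts (CPM at TMM-scaled library sizes, log axis) of the named genes in each of the 6 RNA-seq libraries, with the group mean and SD (n = 3). Camp lies between 5848 and 9950 CPM in the low libraries and between 580.0 and 705.0 CPM in the high libraries.

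The list of neutrophil secondary granule and maturity genes was lower as a set (camera adjusted p = 5.25e-76; adjusted p = 0.0399 with an estimated correlation). All 22 tested members lay below 0, with a median log2 fold change of -2.45. Of these, 14 fell over all genes tested and 22 adjusted over the list alone. Ltf, the iron-binding lactoferrin, fell from 1889 to 295.2 CPM (log2 -2.68 ± 0.24 SE), and Stfa2l1, a stefin with close copies, had -2.65 ± 0.22. Csf3r, Mmp8 and Ly6g were named after their values were seen. Differences were smaller for Csf3r, the G-CSF receptor, at -0.66, and for Mmp8, neutrophil collagenase, at -0.75, both not called over all genes. Ly6g, the surface antigen of mature mouse neutrophils, was at 8.52 CPM in Nrp1 low and 4.26 CPM in Nrp1 high (adjusted p = 0.434).

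The list of primary granule and myeloid progenitor genes was also lower (camera adjusted p = 3.86e-25; adjusted p = 0.0796 with an estimated correlation). Of 18 members 9 fell over all genes, 10 adjusted over the list alone, and the median was -1.49. Ms4a3, a membrane protein of granulocyte-monocyte progenitors, had a log2 fold change of -2.32, Fcnb, a ficolin of the lectin complement pathway, -2.58, and the serine proteases Prss57 and Prtn3 -2.05 and -1.59. Cd34, Sox4 and Hmgn1, named after their values were seen, had -0.18, 0.37 and 0.32, with adjusted p of 0.814, 0.668 and 0.490. Together the 2 granule lists held 23 of the 105 lower genes. Any of the 44 lists held 36 of them.

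Markers of other blood cells moved with these genes. The megakaryocyte and platelet list was lower (adjusted p = 1.25e-10; adjusted p = 0.0399 with an estimated correlation; median -1.79). Of 17 members 3 fell, and 6 adjusted over the list alone. The 3 were Ppbp, a platelet chemokine, from 15.3 to 1.30 CPM, Gp5, a subunit of the von Willebrand factor receptor, from 7.73 to 1.11 CPM, and Itga2b, the platelet integrin alpha IIb, from 8.13 to 1.96 CPM. In the basophil, mast cell and eosinophil list, 1 of 14 members fell, 5 adjusted over the list alone (adjusted p = 6.94e-05; adjusted p = 0.169 with an estimated correlation). That member was Hdc, histidine decarboxylase, from 37.4 to 9.33 CPM. The lists for B cell, T cell, NK and innate lymphoid cell, erythroid, endothelial and stromal genes were not called, and none of their members was called over all genes tested. This does not show them equal between the fractions. Log2 fold changes of single members ran from -2.49 to 0.56 in the NK and innate lymphoid list. In the T cell list they ran from -0.77 to 2.31.

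The 3 lists of monocytes and macrophages were lower as sets, with members above and below 0 in each. The non-classical monocyte list was lower (median -0.59, adjusted p = 4.91e-05; adjusted p = 0.0796 with an estimated correlation), with 2 of 22 members lower and 7 adjusted over the list alone. These 2 were Pglyrp1, an antimicrobial peptidoglycan-binding protein of granules, at -2.57, and Cd9, a tetraspanin, at -1.50. In the classical monocyte list 2 of 20 fell, 7 adjusted over the list alone, and 2 more were higher on that basis (adjusted p = 0.000163; adjusted p = 0.265 with an estimated correlation). The 2 that fell were Chil3 and Cd177, a neutrophil surface protein that the neutrophil list also holds. F13a1, coagulation factor XIII A, was at 881.2 against 517.6 CPM (log2 0.77, adjusted p = 0.246), and Cd14, the endotoxin co-receptor, had -1.33 (adjusted p = 0.234). Ccr2, a chemokine receptor named after its values were seen, was at 809.8 against 463.3 CPM (log2 0.81, adjusted p = 0.356). F13a1 and Ccr2 were the 2 that were higher adjusted over the list alone. Of the 20 classical members 14 lay below 0 and 6 above. The macrophage list was lower (median -0.46, adjusted p = 0.000113; adjusted p = 0.0985 with an estimated correlation), with 0 of 28 members called by edgeR over all genes and 9 adjusted over the list alone. Vcam1, an adhesion molecule of splenic macrophages, had -1.21 and Slc40a1, the iron exporter, -1.35.

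Further lists that were lower held a single called member or none. Iron and haem handling (adjusted p = 0.000298; adjusted p = 0.0985 with an estimated correlation) held Lcn2, a siderophore-binding granule protein, at -2.43, and 5 of 22 were lower adjusted over the list alone. The lysosome list (adjusted p = 0.00114; adjusted p = 0.686 with an estimated correlation) held Cd63, a tetraspanin of granules and lysosomes, at -2.73, with 2 of 32 adjusted over the list alone. Complement (adjusted p = 0.0391; adjusted p = 0.265 with an estimated correlation) held C5ar1, the C5a receptor, at -2.25, with 3 of 20 lower and 1 higher adjusted over the list alone. The median of the complement list was -0.16 and turned to 0.01 under library totals, a scaling tried after the data were seen that moved the fold changes of all genes by a median of 0.19. The complement list was not called without Nrp1 low replicate 2 (adjusted p = 0.102) or high replicate 1 (adjusted p = 0.0658). The medians of the other called lists kept their sign under TMM, RLE, upper-quartile and library-total scaling. Nuclear oxidative phosphorylation and reactive oxygen genes were lower as lists (both adjusted p = 0.00383; adjusted p = 0.813 and adjusted p = 0.451 with an estimated correlation), with no member called over all genes or adjusted over the list alone. The nuclear oxidative phosphorylation list was not called without Nrp1 low replicate 1 (adjusted p = 0.0506), without low replicate 3 (adjusted p = 0.068) or with library totals (adjusted p = 0.0614). Glycolysis was lower too (adjusted p = 0.0180; adjusted p = 0.346 with an estimated correlation), with 0 of 26 over all genes and 1, the hexokinase Hk3 at -1.11, adjusted over the list alone. It was not called without Nrp1 high replicate 1 (adjusted p = 0.0512) or with library totals (adjusted p = 0.0792).

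Ribosomal protein genes (median 0.42, adjusted p = 6.58e-05; adjusted p = 0.813 with an estimated correlation) and mitochondrially encoded genes (median 0.63, adjusted p = 0.00584; adjusted p = 0.639 with an estimated correlation) were higher in Nrp1 high as lists, with no member called on either basis. Their examples were Rps2 at 0.74, Rpl5 at 0.86, mt-Nd2 at 1.19 and mt-Nd5 at 0.98. Both lists were fixed beforehand as signs of RNA quality and handling, which were not told apart here from a difference between the fractions. Without Nrp1 high replicate 1, the library with the highest mitochondrial share, neither list was called (ribosomal adjusted p = 0.114, mitochondrial adjusted p = 0.0846).

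**Figure D2:**
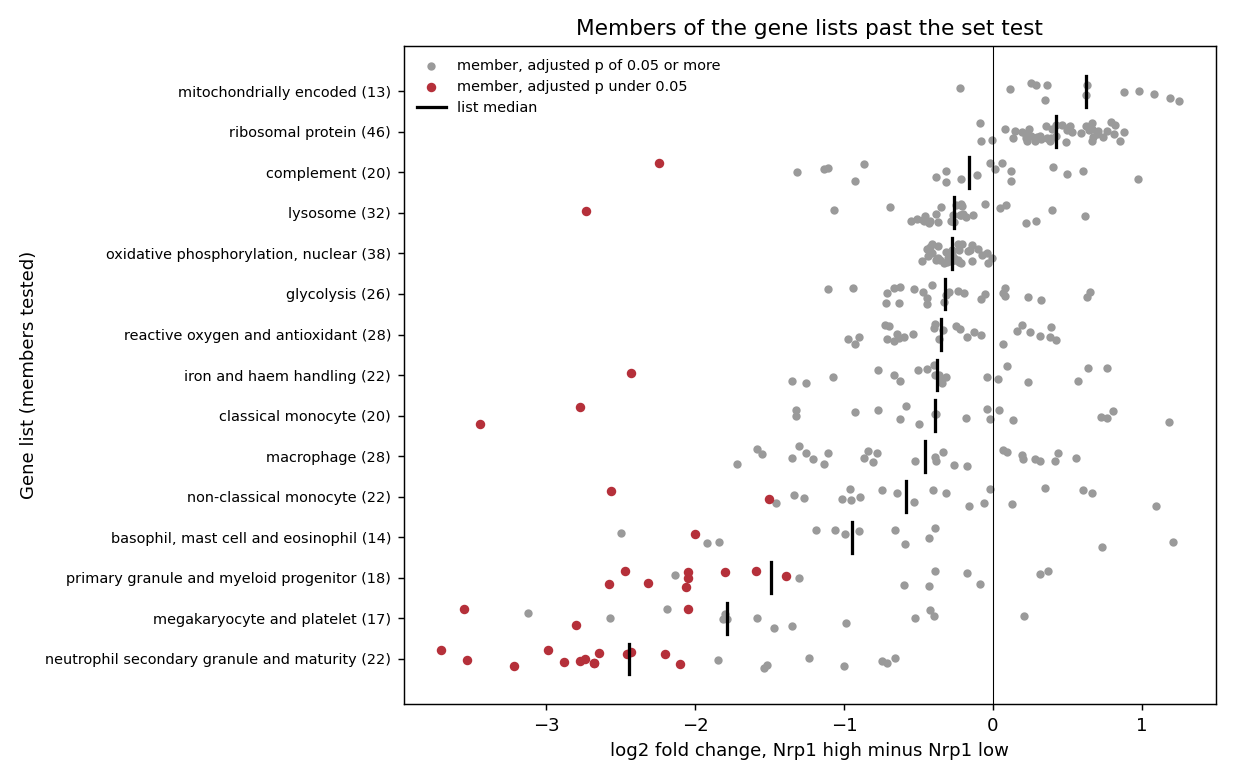
Log2 fold changes, Nrp1 high minus Nrp1 low, of the tested members of the 15 lists past the set test; each point is a gene, red where its adjusted p is under 0.05, and the bar is the list median. The neutrophil list has the lowest median, -2.45, with 14 red points.

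Lists tied to the genes fixed as subjects were not called by camera. The semaphorin, plexin and VEGF list, which holds Nrp1, had a median of 0.33 (adjusted p = 0.376), with 0 of 20 members called over all genes or adjusted over the list alone. In the Kruppel-like factor list Klf5 fell from 20.8 to 6.19 CPM (log2 -1.75 ± 0.29 SE, adjusted p = 0.0463), 1 of 13 members on both bases. In the p38 MAPK list Mapk13, the gene of p38 delta, fell from 122.7 to 31.8 CPM (adjusted p = 0.00825), 1 of 27 on both bases. The mTORC1 list had 0 of 30 members called on either basis, and Lamtor2, a subunit of the Ragulator complex, had -0.70. Of the suppressive effectors of myeloid cells 0 of 25 were called over all genes. Adjusted over the list alone, Trem2, a lipid-sensing receptor, at 0.94, and Il1rn, the interleukin-1 receptor antagonist, at -1.34, passed. With all libraries this list was not called by camera (adjusted p = 0.0872) but was called lower by fry (adjusted p = 0.0232). Camera called it lower without Nrp1 low replicate 2 (adjusted p = 0.0482), low replicate 3 (adjusted p = 0.0454) or high replicate 3 (adjusted p = 0.0253). In the arginine and nitric oxide list 0 of 19 passed on either basis, and Ass1, argininosuccinate synthase, had 0.73.

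Of the 44 lists 15 were called, 13 lower and 2 higher, and 2 of the 15 with an estimated correlation. The 29 others had camera adjusted p between 0.0599 and 0.950. These were 0.0599 for NF-kB, 0.0834 for immediate early, 0.0872 for myeloid transcription factor, 0.112 for erythroid, 0.144 for NK and innate lymphoid, 0.174 for fetal programme and 0.177 for phagocytic receptor genes. MHC class II had 0.376, the unfolded protein response 0.443, endothelial 0.473 and stromal genes 0.5. Cholesterol synthesis, plasmacytoid dendritic cell, cell cycle, TGF-beta and interferon gamma genes had 0.635, and mTORC1, chemokine receptor and integrin, B cell and T cell genes 0.771. Conventional dendritic cell genes had 0.855, pattern receptors, cholesterol efflux and p38 genes 0.932, and arginine, type I interferon and Kruppel-like factor genes 0.950. NF-kB genes were called lower without Nrp1 high replicate 1 (adjusted p = 0.0291), immediate early genes without high replicate 2 (adjusted p = 0.0136) and myeloid transcription factors without low replicate 1 (adjusted p = 0.0358). By fry with all libraries, NF-kB genes were called lower (adjusted p = 0.0232). Fry also called phagocytic receptor genes and myeloid transcription factors lower (both adjusted p = 0.023). Adjusted over the list alone, 5 phagocytic receptor genes were lower and 1 higher, 5 myeloid transcription factors lower, 2 NF-kB genes lower and 2 chemokine receptor or integrin genes each way. Within the uncalled lists the members called over all genes were lower. Gfi1 at -2.05 and Cebpe at -2.47 are transcription factors of granulocyte differentiation, Cxcr2 at -2.46 is a chemokine receptor of neutrophils, Mgl2 at -2.38 a C-type lectin and Inhba at -3.19 an activin subunit. In 8 uncalled lists the median had the opposite sign to the test, and the mean had it in the T cell, mTORC1, pattern receptor, cholesterol efflux, p38 and Kruppel-like factor lists.

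The ATAC comparison asks where chromatin accessibility differs between the same fractions. In the authors' deposited table, 3082 of 40796 regions had an FDR under 0.05, 1046 with a positive fold (higher in Nrp1 high, as the comparison is named) and 2036 with a negative fold. Introns of Nrp1 held 2 regions with positive folds past an FDR of 0.05 in the authors' deposited table, 1.47 (chromosome 8, 128419897 to 128420296, FDR 0.000351) and 1.5 (128431055 to 128431454, FDR 0.000833). A region in another Nrp1 intron had -0.39 (128491462 to 128491861, FDR 0.0296) in the authors' deposited table, and the promoter region of Nrp1 (128357270 to 128357669) had -0.16 (FDR 0.516). The promoter region of Sema4a (chromosome 3, 88454750 to 88455149) had a fold of -0.68 (FDR 0.0129) in the authors' deposited table. For Mapk14 the authors' deposited table gives -0.58 in a distal intergenic region (chromosome 17, 28750550 to 28750949, FDR 0.0478).

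No region of Klf4, Nos2 or Mtor passed, with lowest FDRs of 0.416, 0.132 and 0.438 in the authors' deposited table. Among regions of the neutrophil list that passed in the authors' deposited table, 3 were positive and 2 negative (Fisher's exact p = 0.344, added after the data were seen), the negative ones at the promoters of Ltf (-0.62) and Mmp8 (-0.66). In the primary granule list 1 was positive and 1 negative in the authors' deposited table. Of the genes named by the rule, positive folds there were 1.09 at the promoter of Camp (chromosome 9, 109849351 to 109849750, FDR 0.00244), 1.11 at S100a9 (chromosome 3, 90695573 to 90695972, FDR 0.00378) and 1.72 at Cstdc5 (chromosome 16, 36367429 to 36367828, FDR 0.000676). Itgb2l had 1.65 in an intron (chromosome 16, 96439855 to 96440254, FDR 7.67e-06) and Chil3 1.09 in an intergenic region (chromosome 3, 106172482 to 106172881, FDR 0.000588), in the authors' deposited table. Chil1, Tuba8 and Mogat2 had folds of -0.25, 0.66 and 0.01 that did not pass there, and the promoter of Ugt1a6a had -0.68 (FDR 0.0134).

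The largest positive folds in the authors' deposited table were 3.45 at the promoter of Gm45332, then 3.27 near Myl1, a myosin light chain, 2.94 near Gm6075, 2.87 near Glrx3, a glutaredoxin, and 2.82 near Gm27452. The largest negative folds there were -3.11 near Gm28196, -2.64 near Gm24626, -2.49 in Anxa13, an annexin, -2.30 near Gm49908 and -2.14 near Gm48662.

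Among promoter regions of the authors' deposited table, 1131 of 19352 passed, 344 positive and 787 negative. In introns 317 were positive and 607 negative, and in distal intergenic regions 345 and 572. Regions of the chemokine receptor and integrin list that passed were 0 positive and 13 negative in the authors' deposited table. They included the promoter of Ccr2, the CCL2 receptor of monocytes, at -0.82, and regions of Ccr7, Cd44, Cxcr4 and Gpr183 at -1.08, -0.78, -0.66 and between -1.05 and -0.61. Fisher's exact test of that split against all regions that passed gave p = 0.00639, adjusted p = 0.275 over 43 lists, a comparison added after the data were seen. The smallest adjusted p of the 43 was 0.275. Among macrophage regions of the authors' deposited table, 1 was positive, at the promoter of Slc40a1 (0.65), and 6 were negative, among them introns or flanks of Mertk (-1.51) and Adgre1 (-0.59). The genes of this paragraph were chosen after their values were seen.

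At FDR under 0.01 the authors' deposited table held 1000 regions, 428 positive and 572 negative, and at FDR under 0.05 with an absolute log2 fold of at least 1 it held 997, 479 positive and 518 negative. The sign of the fold rests on the name of the comparison alone.

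**Figure D3:**
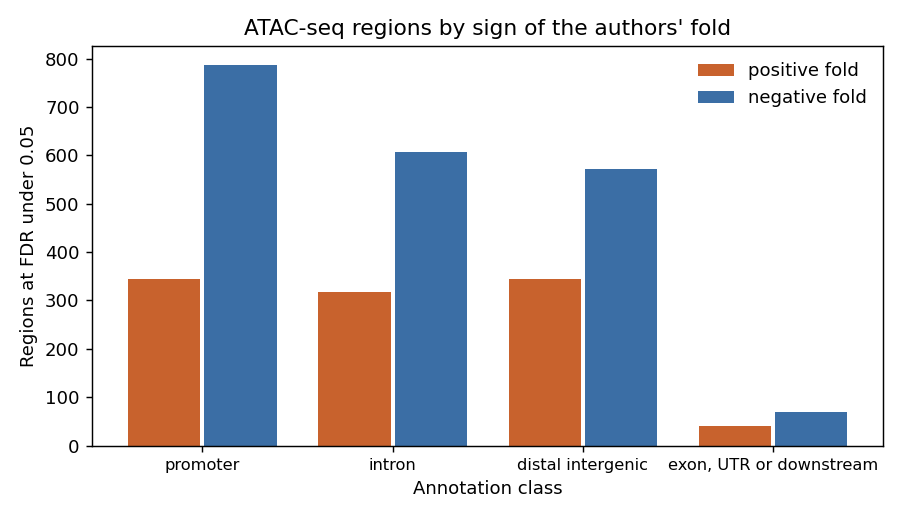
Number of ATAC-seq regions at FDR under 0.05 in the authors' deposited table, by annotation class and sign of the fold. Negative folds outnumber positive ones in each class, 787 against 344 in promoters.

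Setting the assays side by side asks whether promoters and transcripts differ in the same direction. Among genes past both thresholds, 12 had promoter regions of a single direction in the authors' deposited table. Of 11 genes lower in RNA, 9 had a positive promoter fold: Camp, S100a9, Cstdc5, Stfa2l1, Klf5, Tnfsf13b, Slco4c1, Tinagl1 and 4930438A08Rik, named after their values were seen. Ltf and Hdc had negative folds in the authors' deposited table (-0.62 and -1.22) and lower RNA. Ugt1a6a, higher in RNA, had a negative one. Fisher's exact test gave p = 0.25, the smallest these totals allow. Leaving out an RNA library left between 0 genes (without Nrp1 high replicate 3) and 13 (without low replicate 1) past both thresholds. It left 8 without low replicate 2, 7 without high replicate 2, and 6 without low replicate 3 or high replicate 1. With DESeq2's calls for 35 genes, 26 of them opposite in direction, p was 0.00493. Set against tested genes that RNA did not call, of which 29.6% had a positive promoter (222 positive, 527 negative), the share of 9 of 11 differed (Fisher's exact p = 0.000588, added after the data were seen). Those shares cover promoters past the FDR threshold only. Genes are not independent replicates, and Stfa2l1 and Cstdc5 are stefins with close copies, so these Fisher p-values may be too small. Over all 81 genes called lower with a promoter region in the authors' deposited table, 45 had a mean promoter fold above 0 and 36 below. With the fold read the other way these signs would turn, and the 9 genes would be lower in both assays. Across 10821 genes, which are not independent replicates, the mean promoter fold and the RNA log2 fold change had a Spearman rho of -0.0912 and a Pearson r of -0.129, each with a permutation p of 1e-05, the smallest these permutations can give.

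**Figure D4:**
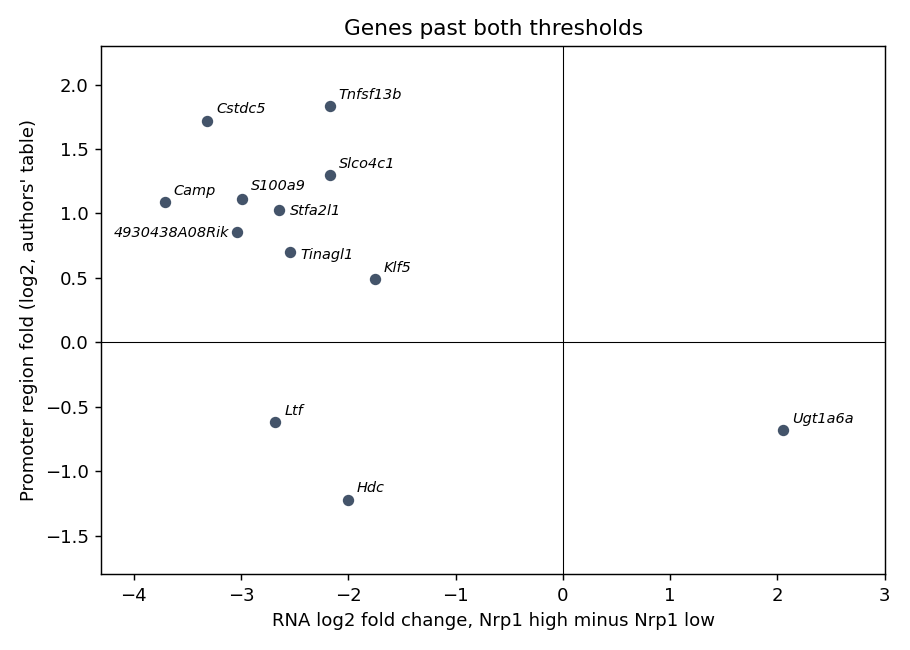
Promoter region fold (log2, the authors' deposited table) against RNA log2 fold change, Nrp1 high minus Nrp1 low, for the 12 genes past both thresholds; each point is a promoter region. The upper left quadrant holds 9 genes, the lower left 2 and the lower right 1.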

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

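Of the tests in this part, those added after the results were seen were the division of counts by 4, library totals for gene lists and the comparison of genes called lower with genes not called. The RNA count of 106 (1 higher, 105 lower) stayed within 1.5 times under RLE factors (108), upper-quartile factors (112), limma-voom (120), no filter (125), a filter at 10 CPM (122), a log2 threshold of 1 and counts divided by 4 (132). DESeq2 called 393 (81 higher, 312 lower; 7952 adjusted p were NA), and adjusted p under 0.01 left 39, all lower, with 0 higher. The single higher gene became 2 with upper-quartile factors, 4 with no filter and 3 with counts divided by 4. Leaving out a library gave 0 to 125 genes, 0 to 5 higher and 0 to 120 lower: 0 without high replicate 3, 28 without high replicate 1, 29 without low replicate 3, 50 without high replicate 2, 81 without low replicate 2 and 125 without low replicate 1. Each such fit has fewer samples. With the replicate number as a block edgeR called 0 genes, 0 higher and 0 lower, with 943 at unadjusted p under 0.05. Same-numbered libraries deviated with correlations of -0.237, -0.24 and 0.021, and no low library correlated best with its own number. With 3 libraries per group these values cannot decide whether libraries of equal number share animals or a sort. The labels do not say, so the block fit stands as an alternative. All 106 called genes kept their sign where tested, which the lack of overlap between their groups made nearly certain beforehand.

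Of 181 named genes 36 were called. These 36 remained called with DESeq2, RLE factors, no filter, counts divided by 4 and without low replicate 1. None remained so under the block or without high replicate 3, and 18 to 29 did in the other fits that leave out a library. No called named gene changed sign in these fits, but their groups did not overlap, so this adds no support. No called list changed the direction of its test, but the median of the complement list turned to 0.03 without high replicate 1 and to 0.013 with library totals. The 15 called lists became 2 with an estimated correlation, 13 by fry (9 of the 15), 14 with the block, 15 with RLE factors, 13 with library totals, and 12 to 16 without a library. The cause was not tested.

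The ATAC count of 3082 (1046 positive, 2036 negative) became 1000 (428, 572) at FDR under 0.01 and 997 (479, 518) at an absolute log2 fold of at least 1, by stricter thresholds alone, and promoter regions numbered 812 within 1000 bases against 1131. Fisher's p of 0.25 was 0.25 within 1000 bases, 0.167 with every region of a gene, 0.231 without low replicate 1, 0.00493 with DESeq2's calls and 0.000588 for genes called lower against genes not called. In the 8 other settings no test was possible. The block and the fit without high replicate 3 left 0 genes, and the others left 6 to 8 genes lower in RNA, 5 or 6 of them with a positive promoter fold, and none higher. Spearman's rho of -0.0912 ranged from -0.102 to -0.0638, -0.0903 with the block, past its test each time. At this depth and number of libraries 7% of 2-fold and 82% of 4-fold changes were recovered on simulated counts, and depth was not varied. ATAC replicates were not left out, since only the authors' comparison was used.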

Other observations

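Of the 105 genes lower in Nrp1 high monocytes, 69 lay in none of the 44 lists. The genes of this paragraph were chosen after their values were seen. They were picked singly, and no test of a group was run on them. Alox5, the 5-lipoxygenase, fell from 131.0 to 28.9 CPM (log2 -2.18 ± 0.28 SE, adjusted p = 0.0150) and Lta4h, leukotriene A4 hydrolase, from 1008 to 234.5 CPM (-2.10 ± 0.24, adjusted p = 0.00825). Mgst2, a microsomal glutathione transferase, had -1.73 and Alox12, the platelet lipoxygenase, -4.43. Fpr1, the formyl peptide receptor, had -1.69, Ffar2, a receptor for short-chain fatty acids, -2.42 and Gpr84, a receptor for medium-chain fatty acids, -1.69. Anxa1, annexin A1, fell from 2302 to 567.4 CPM (-2.02 ± 0.32, adjusted p = 0.0387), and Hvcn1, the proton channel, from 165.8 to 39.6 CPM.

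Of the tests in this part, those chosen only after the results were seen are the 2 on cell mixtures and that on the promoters of genes lower in RNA. On the 106 called genes, the 10 splits of the 6 RNA libraries into 3 and 3 are too few for a share under 0.05: 1 split, the real one, gave as many, and the highest of the others gave 0. At an unadjusted p under 0.05 the real split gave 1744 genes and a mixed split (low replicates 1 and 3 with high replicate 2) 2774, of which none was called after adjustment. Those libraries had the lowest values on the first principal component. They also had the lowest shares of mitochondrially encoded genes and of CT010467.1. Across this mixed split the libraries did not overlap for Sema4a, Klf4, Mapk14 and Mtor, and did for Nrp1. What sets these libraries apart was not tested.

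The fall of granule genes in Nrp1 high RNA is the first pattern, and scaling is argued against as its cause, since the median of the called lower genes stayed at or below -2.06 over TMM, RLE, upper-quartile and library-total scaling. On a Nrp1 low sort less pure for every other cell type, 120 markers of 7 types were examined. These B, T, NK, erythroid, endothelial, stromal and plasmacytoid dendritic cell markers had a median of -0.118 (95% bootstrap interval -0.278 to 0.0251). Of the 120 markers 14 lay below -1. The 7 lists were chosen after the set test had left them uncalled, so a median near 0 followed from that choice. It shows no common fall for these 7 types and decides nothing on others. These 7 types leave out the megakaryocyte and platelet list (median -1.79) and the basophil, mast cell and eosinophil list (median -0.95), which were lower, so cells of those types stay open. Granulocytic cells in the Nrp1 low sort remain a candidate explanation as a hypothesis: 18 of 22 neutrophil list members lay at or below -1, among them the abundant Ngp (12327 against 1065 CPM) and Camp, while Ly6g, Csf3r, Mmp8 and Mcemp1 did not, and all 22 were also detected in every Nrp1 high library (3 are held by another list). The descriptions of the RNA samples hold the name M_MDSC. Whether the gate removed such granulocytic cells still cannot be told, since its markers other than Nrp1 are not given. Monocytes at an earlier stage that express these genes, a difference tied to Nrp1 itself, stay open too.

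Opposite signs of promoters and transcripts are the second pattern. If the deposited fold ran low over high, rho would lie below 0 and the Nrp1 regions would be lower on average. The first holds (rho = -0.0912) and the second does not (mean fold of the 3 Nrp1 regions that passed 0.862), while all 8 Nrp1 regions had a median of -0.07, so the direction cannot be told apart from these values. With the fold as named, the 81 genes called lower had a median promoter fold of 0.0322, above the -0.0367 of all 10821 genes (permutation p = 0.0187). That reading argues against promoters of these genes following their RNA as a set. Set against 0 alone, 45 lay above and 36 below (exact sign test p = 0.374). With the fold read the other way the signs would turn, and genes are not independent. Whether promoters follow their RNA therefore stays open with the direction of the fold. Batches of ATAC libraries and a biological difference between chromatin and transcript stay open and untested.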
